A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

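RNA from chemostat cultures of S. cerevisiae was measured in 6 samples, 1 array each, 3 of the wild type at 10 mM 3AT and 3 of gcn4Δ at 0.1 mM 3AT. The deposited values are intensity values on a linear scale, 1 per probe set and array, made with RMA per the submitters' processing notes. The RMA version, and whether the 6 arrays were normalized in 1 run, are not given in the sources used here. RMA subtracts background, sets the arrays to one distribution and combines the probes of a set, so it evens out any change that would move most genes together. Medians and quartiles of the arrays differed little, and log2 of the deposited intensities was taken here with no further scaling and no pseudocount. All 6 sample columns were used, and 0 columns belonged to other samples.

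Of 10928 probe sets, 7244 had 1 gene name in the platform annotation, 1 had several and 3683 had none here. Names were updated through the gene identifier of the R64 reference table for 12 symbols, and 5498 probe sets matched S. cerevisiae genes. They cover 5449 genes, of which 47 have more than 1 probe set. The brightest probe set on average stood for a gene, with the mean of its probe sets as an alternative. Of the genes called, 18 rest on probe sets that can bind near-identical genes. The array build is not given in the sources used here, so no coordinates are printed, and the reference table served for names and neighbours only. The other 1747 named probe sets matched no S. cerevisiae gene. Their 95th percentile on each array was taken as the background level. A gene below it on every array of a group has only a bound there, written as "at least N-fold", from the mean log2 value of the bright group against the mean of the higher of background level and signal on each array of the dim group. This applied to 8 of the genes called. Means ± SD are over linear intensities and log2 changes over log2 means, so their ratios differ slightly.

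Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, gcn4Δ minus wild type, both groups in 1 fit, no covariates), with Benjamini-Hochberg adjustment over the 5498 probe sets and a threshold of 0.05. Fixed gene lists numbering 41 were written before the data were examined, from textbook pathways and regulons of yeast, with markers of MATα and of sporulating diploid cells and genes next to GCN4. The 39 lists with at least 4 measured members were tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted over the lists. Counts of members past the threshold are given over all genes and adjusted over the list alone. The tests, the alternatives, the lists and the rule for naming genes were set before the data were examined, except where said. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

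Genes were named by a rule: GCN4, the 7 HIS genes, ATR1, CTA1 and CTT1 whatever their values. To these were added the 15 largest falls and 15 largest rises among called genes whose groups did not overlap, up to 2 called members per direction of each list described, or the 1 member with the largest change where none was called, and any gene of the mating-type lists, the general control list and the neighbours of GCN4.

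Alternatives were the replicate number as a block, leaving out each array in turn, quantile normalization again, median centring, leaving out the lowest 25% of probe sets by mean, limma with trend and robust variances, array weights, a threshold of 0.01, a 2-fold minimum, the mean of a gene's probe sets, camera with estimated correlations and fry. A filter on the background level was added after seeing the data. A fit without 1 array has a group of 2 and pools the spread of both groups.

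The gene test was tested on simulated data for this comparison, with 5498 probe sets at the real means. The noise was normal and independent between genes and arrays, at the variances that the eBayes step estimated, with no outlying array. The test recovered 43.3% of 67 changes of 0.5 on the log2 scale, 89.6% of 67 changes of 1 and 97.0% of 66 changes of 2. It made 4 false calls among 157, a share that need not hold for the real arrays. A shifted gene list was called and 0 of 36 other lists were, in simulated genes that vary independently, which real genes do not. A test for the Gcn4 binding motif upstream of changed genes had been planned and was not run, because no genome sequence was used here.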

Results

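Transcript levels were measured on microarrays in budding yeast (Saccharomyces cerevisiae, S288C background) grown in chemostats, continuous cultures in which the rate of glucose supply sets the growth rate. All cultures ran at a dilution rate of 0.10 per hour, 30 °C and pH 5. The medium held aminotriazole (3AT), an inhibitor of the enzyme encoded by HIS3 that starves cells of histidine. The series holds 3 arrays of the wild type at 10 mM 3AT and 3 arrays of a gcn4Δ strain at 0.1 mM 3AT. GCN4 encodes the activator that turns on amino acid biosynthesis genes when an amino acid runs short. The comparison asks which transcripts differ between the strains when both grow at one rate in medium with 3AT. Strain and 3AT concentration differ together, so every difference below belongs to the pair of them. The labels do not say whether the replicates came from separate chemostats, so the p-values measure only the spread between these samples, which may be technical.

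The median intensity over probe sets of S. cerevisiae genes lay between 665 and 712 on the 6 arrays. The background level, taken from named probe sets of other genes, lay between 17.9 and 25.2, and 97.1 to 97.9% of the 5449 measured genes were above it on each array. The number of arrays limits the precision of all values. Across probe sets, which are not independent replicates, Pearson's r was 0.987 to 0.993 within gcn4Δ, 0.969 to 0.989 within the wild type and 0.930 to 0.971 between the groups. The first principal component held 63.5% of the variance and separated the strains. The second component held 19.1%, with wild type replicate 1 on one side and wild type replicates 2 and 3 on the other.

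GCN4 (YEL009C) itself was at an intensity of 7289 ± 36.2 (SD, n = 3) in the wild type. On the arrays labelled gcn4Δ it read 14.5, 213 and 11.4 in replicates 1, 2 and 3, so only 1 of the 3 arrays was above background. The fitted log2 change was -7.80 ± 1.04 (SE, adjusted p = 0.0054, limma). Of its chromosomal neighbours 3 were measured, and none of them passed the test. GLC3 read 0.67, UBC8 0.39 and MIT1 0.30 log2 higher in gcn4Δ (adjusted p = 0.0892, 0.332 and 0.249), while 1 of them passed when adjusted over the list alone. These values were 0.43, 0.10 and 0.13 without wild type replicate 1, which had a median deviation of -0.72 from the other wild-type arrays on these genes. GLC3 passed without wild type replicate 2, at 0.86 (adjusted p = 0.0380). A reporter probe set of the array, outside the comparison of genes, read 4665, 5107 and 4810 on the gcn4Δ arrays and 12.2, 8.70 and 308 in wild type replicates 1, 2 and 3 (adjusted p = 0.112, limma over the probe sets left out of the comparison).

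Of the genes that make histidine, 6 of 7 fell in gcn4Δ. HIS3 (YOR202W), whose product is the target of 3AT, fell from an intensity of 3977 ± 253 to 828.8 ± 86.8 (SD, n = 3 each), a log2 change of -2.27 ± 0.11 (SE, adjusted p = 7.08e-05, limma). HIS5 fell by 1.88, HIS7 by 1.74, HIS1 by 1.31, HIS4 by 1.16 and HIS2 by 0.80 on the log2 scale. HIS6 did not pass, at a log2 change of -0.12 (adjusted p = 0.499), or -0.19 without wild type replicate 2 and -0.03 without wild type replicate 1. The list's median was -1.31 and camera with its preset correlation gave an adjusted p of 4.2e-09, against an adjusted p = 0.140 with an estimated correlation. Adjusted over the list alone, 6 genes were lower. ATR1, a transporter that exports aminotriazole, fell by 2.17 (adjusted p = 6.41e-05). Among catalase genes, whose products 3AT also inhibits, CTA1 was at a log2 change of -0.50 (adjusted p = 0.215) and CTT1 at -0.18 (adjusted p = 0.829). CTA1 was at -0.23 without wild type replicate 1 (adjusted p = 0.284). In that fit CTT1 passed the test at -0.78 (adjusted p = 0.0156).

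**Figure D1:**
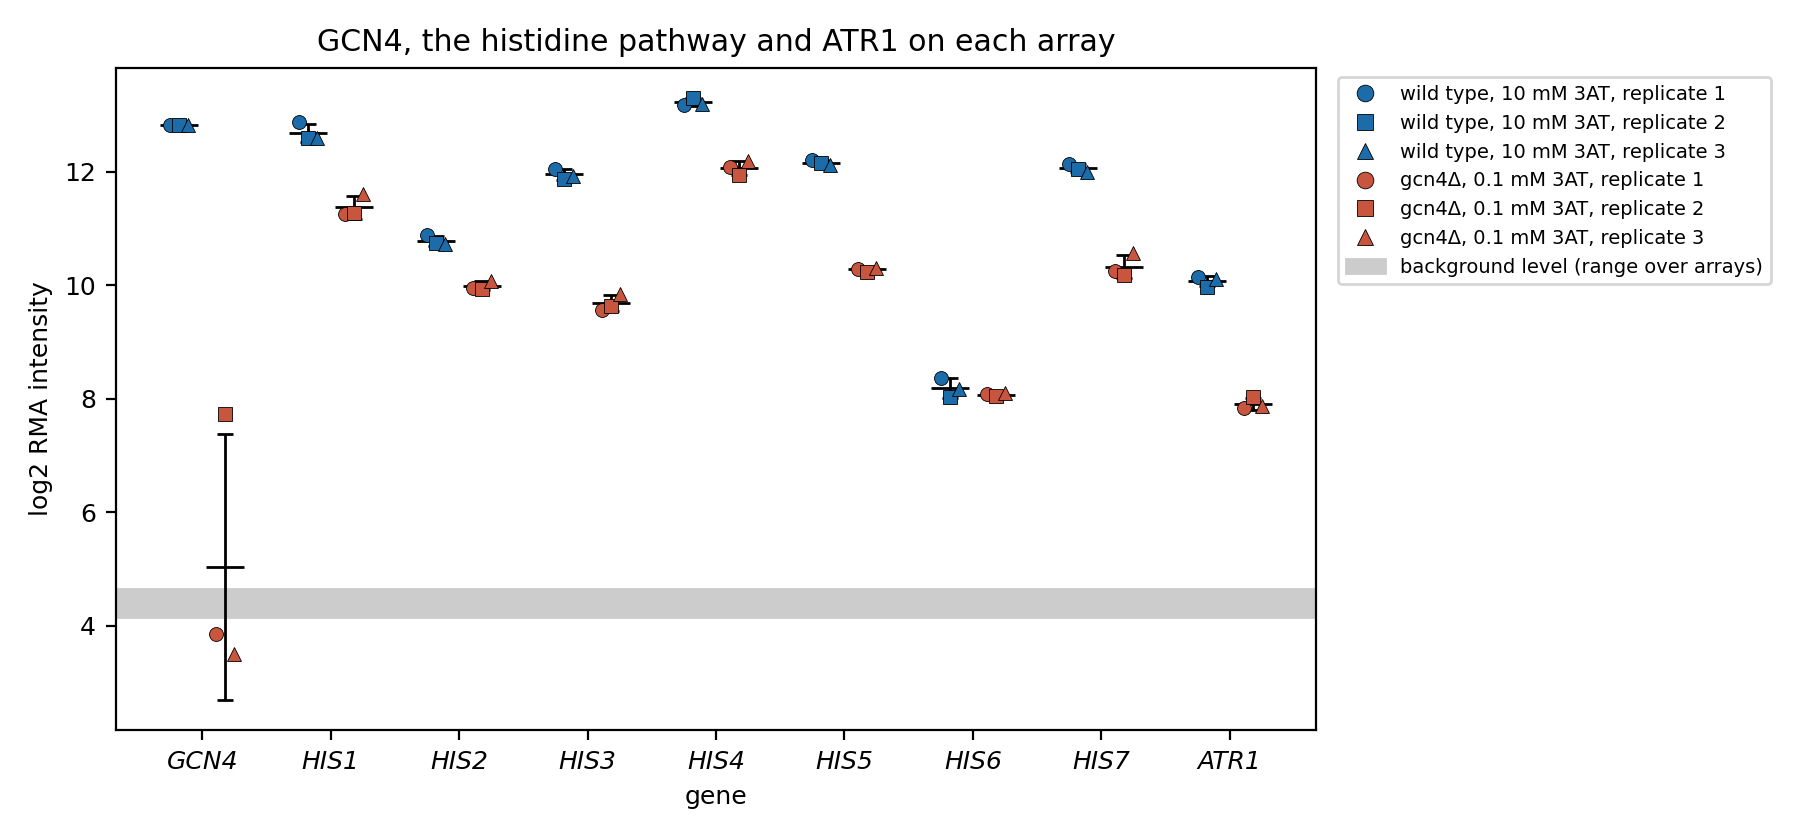
Log2 RMA intensity (vertical axis) of GCN4, the 7 HIS genes and ATR1 (horizontal axis) on each of the 6 arrays, blue for wild type at 10 mM 3AT and red for gcn4Δ at 0.1 mM 3AT, with the group mean and SD as black bars and the background level in grey. GCN4 lies near 12.84 on the wild-type arrays and in gcn4Δ above background only in replicate 2 (7.74), and HIS6 is the one HIS gene whose groups did not differ by the test.

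Across the genome, 618 of 5449 genes (11.3%) differed between the strains at an adjusted p under 0.05. Of these, 291 were higher and 327 lower in gcn4Δ. Large changes were mostly falls: 123 genes fell and 48 rose at least 2-fold, and 32 fell and 12 rose at least 4-fold, with the bound counted for genes below background in one strain. The median size of the change on the log2 scale was 0.78 among genes that fell and 0.57 among genes that rose. The count depended on single arrays: it was 220 without gcn4Δ replicate 1, 258 without gcn4Δ replicate 2, 372 without gcn4Δ replicate 3 and 384 without wild type replicate 3. The genes higher numbered 62, 78, 133 and 149 in those fits, and those lower 158, 180, 239 and 235. Without wild type replicate 1 the count of genes changed was 713, with 355 higher and 358 lower. Without wild type replicate 2 it was 553, with 257 higher and 296 lower.

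The 15 largest falls, GCN4 first, included genes of vitamin B6 synthesis, of the breakdown of aromatic amino acids and of amino acid uptake. SNO1 and SNZ1, neighbouring genes of pyridoxal phosphate synthesis, fell by 4.86 and 3.59 on the log2 scale, and SNZ1 went from an intensity of 7397 ± 98.6 to 640.8 ± 221 (SD, n = 3 each). ARO10 and ARO9, a decarboxylase and a transaminase of the pathway that turns aromatic amino acids into alcohols, fell by 4.76 and 4.41. ADH5, an alcohol dehydrogenase, fell by 3.44. PCL5, the cyclin that targets Gcn4 protein for degradation, fell by 3.08 ± 0.43 (SE, adjusted p = 0.00591). BAP3, a permease of branched-chain amino acids, fell by 2.79, ARG7 of ornithine synthesis by 2.78 and STR3 of methionine synthesis by 2.60. SRY1, a 3-hydroxyaspartate dehydratase, fell by 3.13, YHI9 by 2.55 and BSC5 by 2.52. SRL4 was on no gcn4Δ array above background and was at least 9.22-fold higher in the wild type (fitted log2 change -5.07, adjusted p = 0.000108). OPT2, an oligopeptide transporter, fell by 3.72 and was above background on 1 of 3 gcn4Δ arrays.

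The 15 largest rises in gcn4Δ included transporters and iron genes. HXT13 and HXT10 of the hexose transporter family rose, HXT10 by 2.34 ± 0.32 (SE, adjusted p = 0.00581). HXT13 was on no wild-type array above background and was at least 3.87-fold higher in gcn4Δ (fitted log2 change 3.33, adjusted p = 0.0196). HXT13 read 122, 143 and 25.1 in gcn4Δ replicates 1, 2 and 3, so its change depends much on replicate 3. Its neighbour DSF1 rose by 2.59, from a probe set that near-identical genes may share. The di- and tripeptide transporter PTR2 rose by 2.25, RGI2 by 2.58, HFM1, a meiotic helicase, by 2.32 and SPR3, a sporulation septin, by 2.10. FAT3 rose by 2.92 and was above background on 1 of 3 wild-type arrays. The iron genes FRE2, HMX1, FRE3 and FIT1 rose by 2.51, 2.49, 2.48 and 2.16. HBN1 rose by 2.01. YOR381W-A and YMR244W, both below background on all wild-type arrays, were at least 2.74-fold and at least 2.16-fold higher in gcn4Δ (fitted log2 changes 2.05 and 1.94). The calls of HBN1, HXT13, YOR381W-A and FRE3 were lost without gcn4Δ replicate 1 and also without gcn4Δ replicate 2, with adjusted p up to 0.0730, 0.0790, 0.0935 and 0.137. Those of HXT13, YOR381W-A and FRE3 were lost as well without wild type replicate 3, and that of FRE3 without gcn4Δ replicate 3. Over these omissions their log2 changes were 1.90 to 1.96, 2.88 to 3.48, 1.80 to 2.18 and 2.30 to 2.62.

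Most genes of amino acid biosynthesis fell in gcn4Δ. Of 90 measured, 59 fell, 0 rose and 31 did not pass, with a median log2 change of -0.82, and 66 were lower and 4 higher when adjusted over the list alone. Camera gave an adjusted p of 7.0e-35, and an adjusted p = 0.104 with an estimated correlation. Between 52 and 59 of the genes were lower when any 1 array was left out, and 2 were higher without wild type replicate 1. Arginine synthesis had 7 of 8 genes lower (7 adjusted over the list alone) and the median -1.65, with ARG7 at -2.78 and ARG4 at -2.49 (camera adjusted p = 1.0e-10, and adjusted p = 0.106 with an estimated correlation). Aromatic amino acid genes had 11 of 13 lower (12 adjusted over the list alone) and the median -1.35. After ARO9, the largest fall there was that of ARO3, at -2.23 (camera adjusted p = 3.4e-16, and adjusted p = 0.0615 with an estimated correlation). Branched-chain synthesis had 8 of 11 lower (9 adjusted over the list alone), led by LEU9 at -2.28 and ILV3 at -1.44 (median -0.999, camera adjusted p = 1.5e-09, and adjusted p = 0.109 with an estimated correlation). Lysine synthesis had 5 of 8 lower (7 adjusted over the list alone), led by LYS1 at -1.30 and LYS4 at -1.17 (median -0.73, camera adjusted p = 3.2e-06, and adjusted p = 0.109 with an estimated correlation). Its count was 3 without gcn4Δ replicate 1.

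Genes for aspartate, threonine, serine and glycine had 11 of 17 members lower (12 adjusted over the list alone), among them HOM3, aspartate kinase, at -1.62 and ASN1, asparagine synthetase, at -1.60. Their median was -0.78 (camera adjusted p = 1.1e-10, and adjusted p = 0.0615 with an estimated correlation). Sulfur amino acid genes had 8 of 19 lower, and 9 lower and 1 higher adjusted over the list alone. STR3 and STR2, which convert cysteine to homocysteine, led at -2.60 and -1.89, and 11 members did not pass (median -0.32, camera adjusted p = 0.000147, and adjusted p = 0.190 with an estimated correlation). In the glutamate, glutamine and proline list 3 of 7 genes were lower, led by GLT1, glutamate synthase, at -1.62 and PRO2 at -0.80. Over that list alone 3 were lower and 2 higher, and the list did not pass as a whole in camera (adjusted p = 0.194) but did with fry, lower (adjusted p = 0.0325).

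Purine synthesis had 8 of 11 genes lower, led by ADE1 at -0.78 and ADE8 at -0.73. Over the list alone 9 were lower and 1 higher (median -0.55, camera adjusted p = 8.1e-06, and adjusted p = 0.190 with an estimated correlation). Its count was 3 without gcn4Δ replicate 1 and 3 without gcn4Δ replicate 2, and 5 without wild type replicate 2 or gcn4Δ replicate 3. Of the cytosolic aminoacyl-tRNA synthetases, 7 of 19 were lower (9 adjusted over the list alone), led by KRS1, for lysine, at -1.01 and YDR341C, for arginine, at -0.86 (median -0.25, camera adjusted p = 0.000210, and adjusted p = 0.470 with an estimated correlation). Their count was 3 without gcn4Δ replicate 1, and 4 without gcn4Δ replicate 2 or wild type replicate 3. Their median was -0.16 without gcn4Δ replicate 2. In the list of vitamin B6, thiamine, NAD and riboflavin genes 9 of 21 were lower, led by SNO1 and SNZ1 at -4.86 and -3.59, and 2 were higher. These 2 were SNO3 at 1.14, from a probe set that near-identical genes may share, and the thiamine gene THI4 at 1.02, the latter not past the threshold without gcn4Δ replicate 1, gcn4Δ replicate 2 or wild type replicate 2 (adjusted p up to 0.118, log2 changes 0.93 to 1.06). Over the list alone the counts were also 9 and 2. The median was -0.22 (camera adjusted p = 0.00204, and adjusted p = 0.109 with an estimated correlation), and without gcn4Δ replicate 1 the count lower was 5. Without gcn4Δ replicate 2 it was 6, with a list median of -0.14.

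Amino acid permeases moved in both directions. Of 19 genes 8 were lower, led by BAP3 at -2.79 and DIP5 at -1.76, and 3 were higher, among them the proline permease PUT4 at 1.67 and ALP1 at 1.06. Over the list alone 9 were lower and 3 higher (median -0.48, camera adjusted p = 0.00280, and adjusted p = 0.133 with an estimated correlation), and the count lower was 4 without gcn4Δ replicate 1 and 5 without gcn4Δ replicate 3. Transcription factors of amino acid pathways had 6 of 16 lower, led by UGA3 at -1.42 and BAS1 at -1.01, and 2 higher. The 2 were MET31 at 0.85 and MET32 at 0.49. Over the list alone 7 were lower and 2 higher (median -0.33, camera adjusted p = 0.00268, and adjusted p = 0.110 with an estimated correlation). MET32 kept its call only without wild type replicate 1, with adjusted p up to 0.103 and log2 changes of 0.42 to 0.54 in the other omissions. The count lower in that list was 4 without wild type replicate 3, gcn4Δ replicate 1 or gcn4Δ replicate 2, and 1 gene was higher without any one of the arrays other than wild type replicate 1. Nitrogen catabolite repressed genes split evenly, with 5 of 24 lower and 5 higher (5 and 5 adjusted over the list alone, list adjusted p = 0.882). PUT1, proline oxidase, was at -1.99 and CAR1, arginase, at -1.55, against PUT4 at 1.67 and DAL1, allantoinase, at 1.50. The counts lower and higher were 2 and 3 without gcn4Δ replicate 1, and 3 and 3 without gcn4Δ replicate 2. The count higher was also 3 without gcn4Δ replicate 3.

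The general control list holds mostly genes that control Gcn4 synthesis and turnover. In it 1 of 15 genes was lower and 1 higher, with the same counts adjusted over the list alone (list adjusted p = 0.696). PCL5 was the gene lower. GCN3 was at 0.32 (adjusted p = 0.0457), and its call was lost in each of the 6 omissions of 1 array (adjusted p up to 0.173, log2 changes 0.29 to 0.34). GCN2, the kinase that senses uncharged tRNA, was at 0.12 (adjusted p = 0.614), and at 0.04 without wild type replicate 1 or gcn4Δ replicate 1, 0.22 without wild type replicate 2 and 0.23 without gcn4Δ replicate 2.

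**Figure D2:**
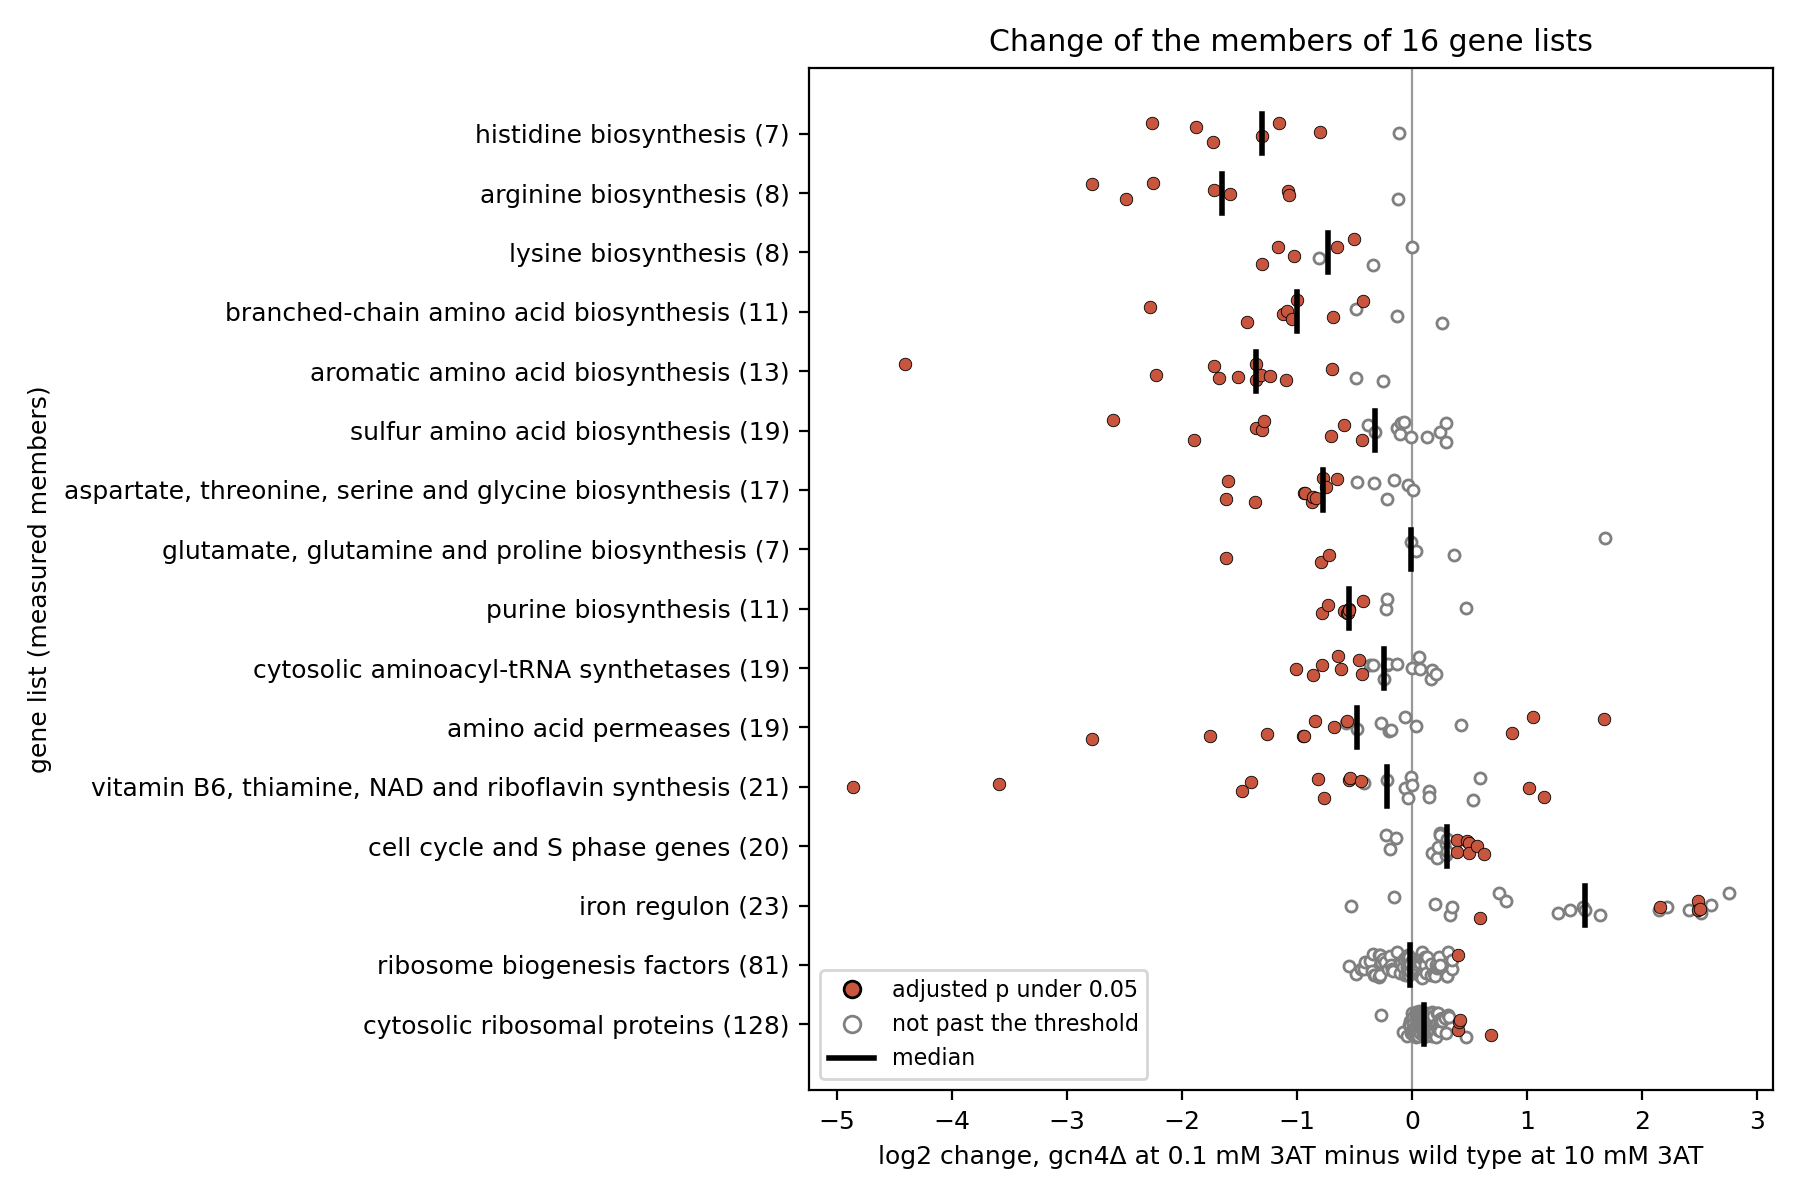
Log2 change, gcn4Δ at 0.1 mM 3AT minus wild type at 10 mM 3AT (horizontal axis), of every measured member of 16 gene lists (vertical axis, number of members in parentheses), with red points for genes at adjusted p under 0.05, open points for the others and a black line at the list's median. Arginine, aromatic and histidine genes have the medians -1.65, -1.35 and -1.31, the iron regulon has 1.51 with most members open, and ribosomal proteins have 0.10.

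In the iron regulon, the genes that respond to low iron and bring it into the cell, 5 of 23 members rose in gcn4Δ and 0 fell, and 14 rose when adjusted over the list alone. FRE2, a ferric reductase, and HMX1, heme oxygenase, led at 2.51 and 2.49. The median was 1.51 (camera adjusted p = 8.1e-06, adjusted p = 0.474 with an estimated correlation and 0.0592 with fry). The wild-type arrays differed widely on this list: over its members the median deviation from the mean of the other wild-type arrays was -1.54 in replicate 1 and 1.21 in replicate 2. The median was 0.76 with 10 genes called without wild type replicate 1, and 2.06 with 16 genes called without wild type replicate 2. With wild type replicate 3 or any one of the gcn4Δ arrays left out, 3 genes were called.

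**Figure D3:**
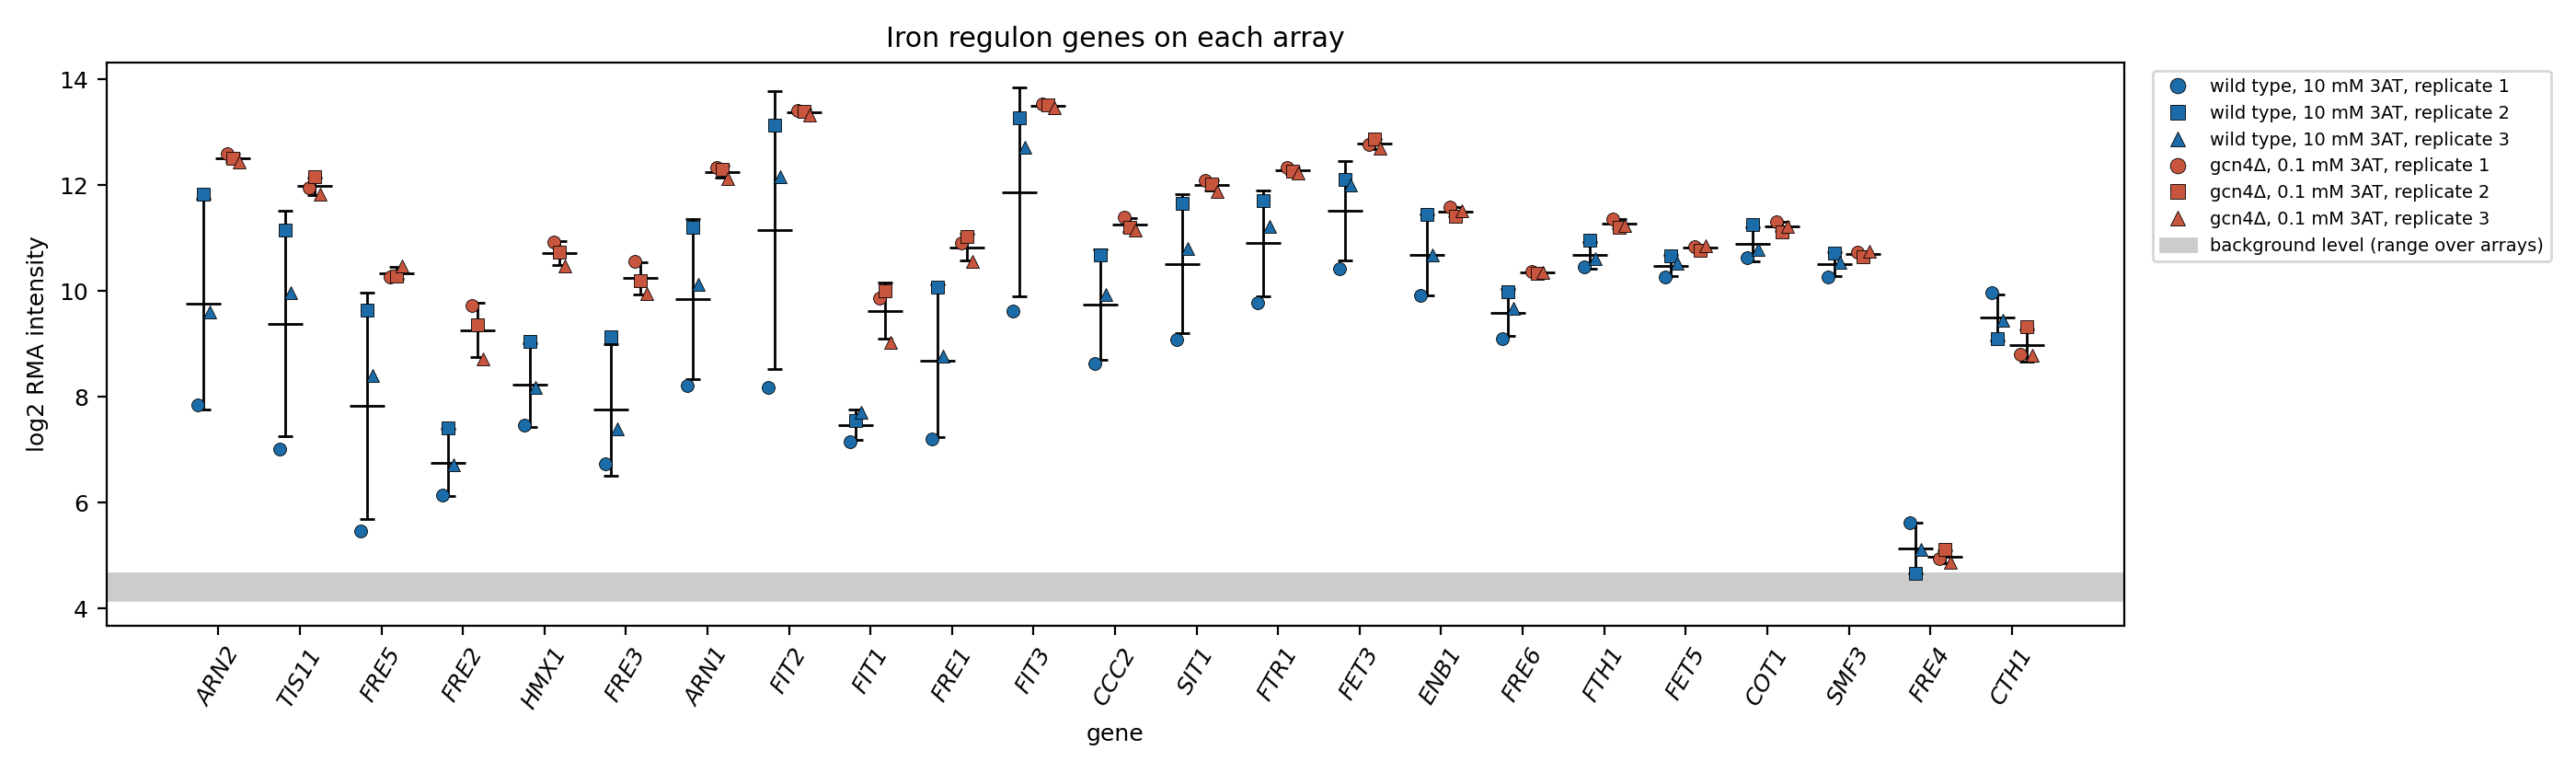
Log2 RMA intensity (vertical axis) of the 23 iron regulon genes (horizontal axis, sorted by log2 change) on each of the 6 arrays, blue for wild type at 10 mM 3AT and red for gcn4Δ at 0.1 mM 3AT, with the group mean and SD as black bars and the background level in grey. On 18 of the 23 genes every gcn4Δ array lies above every wild-type array, and the wild-type arrays are spread wider than those of gcn4Δ on most genes, with replicate 1 mostly lowest. Over all genes measured, 35.7% had groups that did not overlap, in either direction.

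A few phosphate and zinc genes fell. In the phosphate regulon 2 of 16 fell, also when adjusted over the list alone: PHO8, alkaline phosphatase, at -1.26 and VTC4, of polyphosphate synthesis, at -0.67. The median was -0.49 (camera adjusted p = 0.000327, and adjusted p = 0.477 with an estimated correlation). The wild-type arrays were spread on this list too, with a median deviation of -0.61 in replicate 1, -0.02 in replicate 2 and 0.51 in replicate 3, and 7 genes were lower without replicate 1. The count was 1 without wild type replicate 3, gcn4Δ replicate 1 or gcn4Δ replicate 2, each of these omissions taking away the call of VTC4 (adjusted p up to 0.105, log2 changes -0.69 to -0.56). In the zinc regulon 3 of 10 fell, led by ZPS1 at -2.07 and the activator gene ZAP1 at -1.07, and 6 were lower when adjusted over the list alone (median -0.46, camera adjusted p = 0.00645, and adjusted p = 0.133 with an estimated correlation). Without gcn4Δ replicate 1 the count was 0, and without gcn4Δ replicate 2 or gcn4Δ replicate 3 it was 1. In all 3 of these fits ZPS1 and ZAP1 were not past the threshold (adjusted p up to 0.122 and 0.108), nor was ZAP1 without wild type replicate 3. Their log2 changes in the fits that lost them were -2.13 to -1.99 and -1.18 to -0.97.

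Few stress genes passed one by one. Of 36 environmental stress and trehalose genes 2 rose, 1 fell and 33 did not pass. GND2, of the pentose phosphate pathway, was at 1.72, HXK1, a hexokinase, at 0.61 and HSP78, a mitochondrial chaperone, at -0.73. Over the list alone 1 was higher and 1 lower (median 0.31, camera adjusted p = 0.0137, and adjusted p = 0.791 with an estimated correlation). The list no longer passed without wild type replicate 1 (adjusted p = 0.210, median 0.11) or without gcn4Δ replicate 2 (adjusted p = 0.0772). On these genes wild type replicate 1 had a median deviation of -0.52, replicate 2 of 0.22 and replicate 3 of 0.25. GND2 and HXK1 lost their calls without gcn4Δ replicate 1 and without gcn4Δ replicate 2, and HXK1 also without wild type replicate 3 or gcn4Δ replicate 3 (adjusted p up to 0.0914 and 0.151, log2 changes 1.60 to 1.66 and 0.60 to 0.69). The count higher was 4 without wild type replicate 1 and 4 without wild type replicate 2. It was 1 without wild type replicate 3 or gcn4Δ replicate 3, and the count lower was 2 without wild type replicate 1. Of 15 heat shock factor and folding genes 0 passed, also when adjusted over the list alone, and the member with the largest change was YDJ1 at -0.45 (adjusted p = 0.136), or -0.27 without wild type replicate 1. Their median was -0.24 (camera adjusted p = 0.000654, and adjusted p = 0.470 with an estimated correlation). Without wild type replicate 1 their median was -0.14 and 1 was lower. Of 15 unfolded protein response genes 4 fell (4 adjusted over the list alone), led by ERO1, of disulfide formation, at -0.87 (median -0.24, camera adjusted p = 0.00344, and adjusted p = 0.487 with an estimated correlation). The count was 3 without wild type replicate 1 and 1 without any other single array.

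Some cell cycle and S phase genes rose by small amounts. Of 20 genes 7 were higher, 0 lower and 12 higher when adjusted over the list alone, led by POL1, of DNA polymerase alpha, at 0.63 and the cyclin PCL1 at 0.57. The median was 0.30 (camera adjusted p = 0.000161, and adjusted p = 0.106 with an estimated correlation). Without gcn4Δ replicate 1 the count was 0, without gcn4Δ replicate 2 or gcn4Δ replicate 3 it was 2, and without wild type replicate 3 it was 3. POL1 lost its call without any one of the gcn4Δ arrays (adjusted p up to 0.0844, log2 changes 0.62 to 0.64), and PCL1 without gcn4Δ replicate 1 (adjusted p = 0.0525, log2 change 0.56). Of 128 cytosolic ribosomal protein genes 4 were higher, 0 lower and 0 called when adjusted over the list alone. RPS14B was at 0.68 and RPL22B at 0.41, and the median was 0.10 (camera adjusted p = 0.000462, and adjusted p = 0.823 with an estimated correlation). That median was 0.16 without wild type replicate 1. The count was 6 without wild type replicate 1, 1 without wild type replicate 2 or wild type replicate 3, and 0 without any one of the gcn4Δ arrays. RPS14B and RPL22B had adjusted p up to 0.142 and 0.123 in those fits, with log2 changes of 0.51 to 0.78 and 0.40 to 0.43 where the call was lost. Among 81 ribosome biogenesis factors 1 was higher, 0 were lower and 0 were called when adjusted over the list alone (median -0.02, list adjusted p = 0.696). The 1 gene was GAR1 at 0.40, whose call held only without wild type replicate 1 (adjusted p up to 0.110, log2 changes 0.36 to 0.43 in the others).

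With all arrays, the lists that mark cell types did not pass in camera. Of 7 MATa markers 0 passed, also when adjusted over the list alone, with MFA1 at a log2 change of 0.51 (adjusted p = 0.144, list adjusted p = 0.345). Without wild type replicate 3 the list passed (adjusted p = 0.0225), with 2 genes higher and MFA1 at 0.73 (adjusted p = 0.0282). Of the MATα markers 2 were measured and 0 passed, STE3 at 0.28 and SAG1 at -0.06, and the list was too short to be tested. STE3 was at 0.01 without wild type replicate 1 and 0.43 without wild type replicate 3. SAG1 lay between -0.11, without gcn4Δ replicate 3, and -0.01, without gcn4Δ replicate 2, at -0.09 without wild type replicate 2 and -0.04 without wild type replicate 1. Of 12 sporulation markers 2 rose and 1 fell, and 4 rose and 1 fell when adjusted over the list alone. SPR3 was at 2.10, NDT80 at 0.48 and IME1 at -0.43 (list adjusted p = 0.161, though 0.0180 with fry, higher). Without wild type replicate 1 the list passed (adjusted p = 0.0464) with 3 genes higher. NDT80 and IME1 lost their calls in 4 omissions each, without any one of the gcn4Δ arrays and without wild type replicate 3 for NDT80 or wild type replicate 2 for IME1 (adjusted p up to 0.133 and 0.129, log2 changes 0.43 to 0.51 and -0.46 to -0.41). Without wild type replicate 2, gcn4Δ replicate 1, gcn4Δ replicate 2 or gcn4Δ replicate 3 the count lower was 0, and without wild type replicate 3, gcn4Δ replicate 2 or gcn4Δ replicate 3 the count higher was 1. Of 5 common deletion marker genes HIS3 and LYS2 fell, by 2.27 and 1.02, and 2 were lower when adjusted over the list alone (median -0.14, camera adjusted p = 0.00994, and adjusted p = 0.140 with an estimated correlation). Both also belong to the amino acid lists.

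Of the 39 lists tested, 22 passed with camera's preset correlation, 18 lower and 4 higher. With a correlation estimated for each list 0 passed in camera. Lists with an estimated correlation below 0, and so below the preset of 0.01, lost their calls too. Examples are aspartate, threonine, serine and glycine (-0.013), cell cycle (-0.014) and zinc (-0.031). In such lists a higher correlation cannot account for the loss. With an estimated correlation camera takes its degrees of freedom from the arrays, and with the preset one from the number of genes. For the aspartate list the unadjusted camera p went from 1.08e-11 to 0.00184. P-values from the preset correlation thus treat genes as the units. The fry test, which asks only whether a list's genes move one way, called 19 lists, 16 of them among the 22. It did not call iron (adjusted p = 0.0592), phosphate (0.0872), environmental stress (0.308), heat shock (0.0548), the unfolded protein response (0.0548) or ribosomal proteins (0.224). The 3 it called beyond camera were glutamate, glutamine and proline (0.0325), peroxisome (0.0325) and sporulation markers (0.0180).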

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

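What this part reports was chosen only after the data were seen. The probe sets that the comparison leaves out were fitted apart with limma, with variances and an adjustment of their own. Calls from that fit are therefore not on the scale of the calls of genes. Among probe sets without a gene name here, 8 differed between the strains in it at an adjusted p under 0.05. Of these 6 were lower and 2 higher in gcn4Δ. The largest fall was a log2 change of -3.57 and the largest rise 1.17. Which transcripts they measure was not analysed here. Of the 1747 named probe sets that serve as background, 4 were called in that separate fit, 2 higher and 2 lower, so a call near background need not reflect a yeast transcript. A reporter probe set of the array, also outside the comparison, read 308 in wild type replicate 3 against 12.2 and 8.70 in the other wild-type samples and 4665 to 5107 in gcn4Δ.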

How the results depend on the processing

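The background filter was the one setting chosen only after the data were seen. The count of genes changed, with those higher and lower, was 618, 291 and 327, and with the replicate number as a replicate block it was 210, 57 and 153, with 205 of the 618 genes among them. The labels give no pairing beyond the number. Deviations of same-numbered arrays from their group means correlated at -0.34, -0.38 and -0.22, against 0.56 for wild type replicate 2 with gcn4Δ replicate 1. Deviations within a group constrain one another, so these values cannot decide whether arrays were paired. With the block 22 lists passed, and of the 102 named genes called 68 were called. Leaving out each array in turn gave 220 to 713 genes changed, 62 to 355 higher and 158 to 358 lower, and 21 to 24 lists. With array weights, whose estimation stopped before it converged, the counts were 1443, 829 and 614. At an adjusted p under 0.01 they were 224, 61 and 163, and with a 2-fold minimum on the fitted change 174, 51 and 123, both by construction. For the block, the weights and the single arrays the cause was not tested beyond the loss of samples or residual degrees of freedom. Quantile normalization, median centring, the dim filter, trend and robust variances, the mean of probe sets and the background filter gave 531 to 679 genes. GCN4 stayed lower and past the threshold of each setting, from -9.15 to -7.03, with adjusted p from 7.24e-06 to 0.0282. The value of -9.15 comes from the fit without gcn4Δ replicate 2. Both gcn4Δ readings left in that fit were below background, so its size is uncertain. Of the 102 named genes called, 68 were called whichever array was left out. CTT1, not called, lay between -0.78 and 0.16 when each array was left out in turn, at 0.08 without wild type replicate 2 and 0.16 without wild type replicate 3. Of the 22 list calls 0 stayed with estimated correlations and 16 with fry. The 6 lost with fry were iron, phosphate, environmental stress, heat shock, the unfolded protein response and ribosomal proteins (adjusted p = 0.0548 to 0.308), and it called 3 others, glutamate, peroxisome and sporulation markers (adjusted p = 0.0180 to 0.0325). The motif alternatives were not run, since no genome was used here. Signal over background limits little: 87 genes were above background on no array, and 5275 on all 6.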

Other observations

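Carbon and energy metabolism differed in few genes. Of 17 glycolysis and fermentation genes 0 passed, with the largest change in PDC6 at a log2 change of 1.18, or 0.53 without wild type replicate 1 (list adjusted p = 0.696, limma). Of 24 genes of the tricarboxylic acid and glyoxylate cycle 2 were lower, CIT3 at -0.71 and PYC2 at -0.52 (list adjusted p = 0.696). Their calls were each lost without any one of the gcn4Δ arrays, and also without wild type replicate 2 for CIT3 and wild type replicate 3 for PYC2 (adjusted p up to 0.135 and 0.0766, log2 changes -0.77 to -0.68 and -0.55 to -0.50). With wild type replicate 1 left out, 6 were lower and the list passed (adjusted p = 0.00532). Of 33 respiratory genes 1 was lower, CYC7 at -0.45, not past the threshold without wild type replicate 2, wild type replicate 3, gcn4Δ replicate 1 or gcn4Δ replicate 2 (adjusted p up to 0.133, list adjusted p = 0.555), while 2 were lower and 1 higher without wild type replicate 1. Of 15 gluconeogenesis and glucose-repressed genes 2 were higher, REG2 at 1.52 and the lactate transporter JEN1 at 1.41 (list adjusted p = 0.353). The call of JEN1 was lost in 4 omissions, of wild type replicate 3 or any one of the gcn4Δ arrays (adjusted p up to 0.159), and 5 genes were higher without wild type replicate 1. Of the 13 hexose transporters on the fixed list HXT10 was higher, at 2.34, and HXT4 lower, at -1.65 (list adjusted p = 0.696). That list does not hold every member of the family. HXT13, which is not on it, was also higher (fitted log2 change 3.33, adjusted p = 0.0196, limma). Adjusted over the list alone, the counts higher and lower were 0 and 0, 0 and 1, 0 and 0, 2 and 0, and 1 and 2 in these 5 lists.

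Among other pathways, 3 of 19 peroxisome genes were lower, led by PEX21 at -2.06 and PEX14 at -0.78, the latter not called without gcn4Δ replicate 1 (adjusted p = 0.0511). The list did not pass in camera (adjusted p = 0.0816), but did with fry (adjusted p = 0.0325), without wild type replicate 1 (adjusted p = 0.0106) and without gcn4Δ replicate 1 (adjusted p = 0.0346), where 1 gene was lower. Of 18 autophagy and vacuolar protease genes 2 were lower, ATG1 at -1.52 and ATG13 at -0.50 (list adjusted p = 0.993). ATG1 was not called without gcn4Δ replicate 1 or gcn4Δ replicate 3 (adjusted p up to 0.0688), and ATG13 only with all arrays or without wild type replicate 1 (adjusted p up to 0.158 otherwise). Of 9 pyrimidine genes 2 were lower, URA10 at -1.01 and URA4 at -0.95, the latter not called without gcn4Δ replicate 1 or gcn4Δ replicate 2 (adjusted p up to 0.0507, list adjusted p = 0.191). Of 24 ergosterol genes ERG4 was higher at 0.35 and ERG12 lower at -0.52 (list adjusted p = 0.929), both called only with all arrays or without wild type replicate 1 (adjusted p up to 0.204 and 0.151 otherwise). Of 20 oxidative stress genes 2 were lower, CCP1 at -1.40 and GPX2 at -0.49, and 2 higher, OYE3 at 0.81 and OYE2 at 0.46 (list adjusted p = 0.929). CCP1 was not called without gcn4Δ replicate 2 (adjusted p = 0.0557), OYE2 and OYE3 not without gcn4Δ replicate 1 or gcn4Δ replicate 2, OYE3 also not without wild type replicate 2, and GPX2 only with all arrays or without wild type replicate 1 (adjusted p up to 0.0778, 0.111 and 0.179). The count lower was 4 without wild type replicate 1. Of 15 multidrug and aminotriazole efflux genes ATR1 was lower at -2.17, and PDR15 and TPO1 were higher at 0.92 and 0.66 (list adjusted p = 0.696), and 2 genes were lower without wild type replicate 1. Adjusted over the list alone, the counts higher and lower were 1 and 3, 1 and 2, 0 and 2, 0 and 0, 2 and 2, and 2 and 2 in these 6 lists.

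Tests on RNA of the other strain and on the omission of wild type replicate 1 from the iron list were chosen only after the result was seen, and the bound for the latter replaced a first one, 0.5 of the median or 0.75, that the value had passed by only 0.01. The GCN4 signal of 213 on gcn4Δ replicate 2 exceeded the mean of the other gcn4Δ arrays by 2.75% of the wild-type signal, and wild-type RNA mixed into that sample would raise other transcripts by a like percent. Comparison genes were the 10 others at least 8-fold brighter in the wild type than the mean of gcn4Δ replicates 1 and 3. Their median excess on replicate 2 was 2.07% (97.9% sign-based interval 0.861 to 7.31), and 9 of the 10 were above 0. The excess is taken over that same mean, so genes low on replicates 1 and 3 are favoured and part of it is built in. Of 1378 genes of like signal that differed under 1.25-fold between the wild type and that mean, 41.2% were above 0. Among the 10 genes, PCL5 at 15.3% lies far from a uniform share. The lower end of the interval, 0.861, is the value of SRL4, which was below background on every gcn4Δ array. OPT2, the gene not above 0, was above background on only 1 gcn4Δ array, so both values are uncertain. In wild type replicate 3 the reporter signal of 308 exceeded that of the other wild-type arrays by 6.14% of the gcn4Δ signal. For comparison, 14 genes had a mean signal in gcn4Δ at least 4-fold above the mean of wild type replicates 1 and 2. Their median excess in wild type replicate 3 was 1.81% (98.7% sign-based interval -3.12 to 6.59), which neither shows nor excludes gcn4Δ RNA. These genes too were chosen by the arrays that the excess is taken over. A small share of the other strain's RNA may be present on either array, and no biological explanation was tested.

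The iron regulon may follow strain, 3AT concentration or single arrays. Wild type replicate 1 was lowest on this list. Without it the median was 0.76 against 1.51, and 10 genes were called, so the rise was smaller but did not vanish. The 95% sign-based interval of that median over the member genes was 0.48 to 1.42. This interval reflects the spread between genes, which move together (estimated correlation 0.59), and not the spread between arrays. How much of the rise rests on that array is therefore not settled. A drift of change with signal level is argued against, since 0 of 10000 random lists matched on mean signal reached the median, the highest being 0.28. Strain and concentration cannot be told apart, because 0 arrays carry one strain at the concentration of the other. Differences in iron supply between the wild-type samples were not tested. Their median deviations on this list, each from the mean of the other wild-type arrays, ran from -1.54 to 1.21.

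Wild type replicate 1 stood apart from the other wild-type arrays. Its deviations from their mean had an SD of 0.43 on the log2 scale against 0.32 and 0.28 for the other two, with 78 genes at least 2-fold up and 119 down. A trend with signal level left in these values accounts for little of this, since the SD was 0.42 after a loess trend on mean signal was removed. RMA sets the arrays to one distribution, so most of such a trend may have been removed beforehand. A bias of that kind before RMA cannot be judged from these values. After iron, its median deviation was -0.72 on the 3 genes next to GCN4, -0.61 on the phosphate regulon, -0.55 on gluconeogenesis and -0.52 on environmental stress. On these lists wild type replicate 3 deviated the other way by 0.31, 0.51, 0.58 and 0.25. Each deviation is taken from the mean of the other arrays of its group. A low replicate 1 by itself raises the deviations of the others, so the opposite sign is partly arithmetic. No biological explanation was tested.

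Counts of genes at least 2-fold from the other arrays of their group, on both arrays of a pair, were made after the data were seen and were not tested. Over the 9 pairs of a wild-type and a gcn4Δ array, 0 to 12 genes were up on both, 12 for wild type replicate 1 with gcn4Δ replicate 2 and 6 for wild type replicate 3 with gcn4Δ replicate 2. Down on both were 0 to 9, with 9 for wild type replicate 1 with gcn4Δ replicate 3. Over all genes the deviations of the first of these pairs correlated at 0.10, and the highest correlation, 0.56, was that of wild type replicate 2 with gcn4Δ replicate 1.

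The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The count of genes changed was 618 for the real split and at most 20 for the others, so 1 of the 10 splits gave as many, the real one. For genes higher, 291, and genes lower, 327, it was also 1 of 10, with at most 20 in one direction elsewhere. For gene lists the real split gave 22 and the split of wild type replicate 1 with gcn4Δ replicates 2 and 3 against the rest gave 22 as well, so 2 of the 10 splits gave as many. Every other split sets 2 arrays of one strain with 1 of the other and so keeps part of the difference between the strains, which makes these counts no reference free of change.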
